A study of Drosophila melanogaster with 6 samples.

How the data were processed

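RNA was measured on arrays in mesodermal cells that had been sorted by GFP fluorescence from Drosophila melanogaster embryos, with 3 arrays of jumu overexpression and 3 arrays of the control genotype. Groups and replicate numbers were taken from the sample titles. Per the labels, about 2 to 5 µg of total RNA per sample was turned into biotin-labelled cRNA, and per the submitters' processing notes the arrays were processed with the Bioconductor package affy. Its version, the background correction, the normalization and the summary over probes are not given in the sources used here. The deposited values are taken as log2 signals per probe set: the base was read from the range of the values, which runs from about -1.73 to 16.4 and matches log2 of a scanner's intensities. The array medians of the deposited log2 values were 5.43, 5.30 and 5.09 in the jumu arrays and 5.61, 5.64 and 5.38 in the controls. The authors' table therefore did not share 1 distribution over the arrays, and quantile normalization between arrays was applied before testing, by a rule written for that case. Every change below is relative to this scaling.

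The table held 18952 probe sets, of which 183 Affymetrix control probe sets were left out and 18769 were tested. In the platform annotation used, 13647 probe sets had 1 gene, 402 had several, and 4720 had no gene symbol there or were not listed. Symbols were updated through the gene identifier with a RefSeq gene table (Release 6 assembly), which matched 13544 of the single-gene probe sets. The files name no genome build, so no coordinates are given and that table served for names and for which genes are neighbours. A gene was represented by the probe set with the highest mean over the 6 arrays, which gave 11983 genes, 1094 of them with more than 1 probe set. Probe sets with several genes or no symbol were tested but not named.

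Each probe set was tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with the default variance prior, two-sided, no covariates), with Benjamini-Hochberg adjustment over the 18769 probe sets and a threshold of 0.05. "Rose" and "fell" are used for genes past that threshold. Errors beside a log2 change are limma standard errors with 3 arrays per group. The prior had 0.94 degrees of freedom. For bright probe sets it nonetheless set most of the standard error: barr had SDs of 0.013 and 0.017 and an SE of 0.086. No array depth can be given, and the number of arrays limits the precision. On data simulated from these arrays with 18769 probe sets, the test recovered 21 of 62 changes of 1 log2 unit and 33 of 43 changes of 2 log2 units among probe sets above the median level, and 0 of 38 and 1 of 57 below it, with 3 false calls among 58. Only the probe sets in these counts were changed there. With 58 calls against 519 in the real arrays, the adjustment was stricter in the simulation. Its recovery therefore does not carry over directly to the real test.

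Before the data were examined, 26 gene lists were written from general knowledge. They cover forkhead factors, mitosis, DNA replication, cardiac, early mesodermal, founder and fusion, differentiated muscle and visceral mesoderm genes, Wnt and FGF receptor genes, other cell types a sort could hold (blood cell, fat body, nervous system, epidermis and trachea, endoderm, germ line), early embryo patterning, asymmetric division, Notch targets, receptor tyrosine kinase targets, chromatin silencing, heat shock, innate immunity, apoptosis, glycolysis, ribosomal proteins and transgene markers. Of 677 symbols, 668 matched a gene and 490 had a probe set. The entries vap (early mesoderm) and her (Notch targets) matched genes that were not meant; the lists were kept as fixed and tested again without them. The 24 lists with at least 5 measured genes were tested with camera from limma at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Camera was run again with an estimated correlation, and fry was run as another test.

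The genes named were fixed by a rule, also before the data were examined: jumu, polo, CHES-1-like, fz, fz2 and htl; the 12 largest rises and 12 largest falls past the threshold with no overlap between groups; and up to 4 genes with the smallest p in each list. Some further genes of the lists that passed the threshold are named to show which members moved, and these were chosen after their values were seen. The alternatives were median centring, no quantile step, filters on dim probe sets, an intensity trend in the variance prior without and with robust estimation, array weights, the replicate number as a block, leaving out each array, limma's treat at 1.2-fold, an unequal-variance test and the mean over a gene's probe sets. Shifts to the spiked-in control probe sets, and the intensity trend combined with a left-out array, the block or median centring, and the lists without vap and her, were added after seeing the data, as was the log2 signal of 6 under which sizes are given as bounds.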

Results

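RNA from mesodermal cells of Drosophila embryos was profiled in 2 genotypes. In both, the twist driver (twi-GAL4) switched on GFP in the mesoderm, and GFP-positive cells were sorted from embryos aged at 29 °C to late stage 11 or early stage 12. In the overexpression group the same driver also switched on jumu, which encodes a forkhead transcription factor. The jumu transgene is labelled as standing opposite the driver and reporter, and nothing is named in that place for the control. Whether both genotypes carried equal copies of driver and reporter, or the control a matching transgene, is therefore not known. Each genotype had 3 arrays. The series title places the work in the control of cardiac progenitor division by forkhead factors through the mitotic kinase Polo, and the comparison asks which transcripts of sorted mesodermal cells differ when Jumu is made in excess. The labels number the replicates without saying whether they came from separate embryo collections, so the p-values measure the spread between these samples, which may be technical.

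Arrays of 1 genotype resembled each other more than arrays of the other genotype did, most clearly for bright probe sets. Over the 4758 probe sets with a mean log2 signal over 9, Pearson's r across probe sets was 0.993 to 0.995 within a genotype and 0.958 to 0.961 between genotypes. Over all probe sets these ranges were 0.917 to 0.928 and 0.908 to 0.918. The first principal component held 24.9% of the variance and separated the genotypes. It stood little above the others, which held 20.3%, 19.1%, 18.8% and 17.0%. The median SD between replicates fell from 1.23 log2 units in probe sets with a mean log2 signal under 3 and 1.13 from 3 to 6, to 0.20 from 6 to 9, 0.09 from 9 to 12 and 0.05 over 12.

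The transcript of jumu itself was 4.31-fold higher in the overexpression arrays. Its 1 probe set had a log2 signal of 13.56 ± 0.18 (SD, n = 3) against 11.45 ± 0.11 (SD, n = 3) in controls, a log2 change of 2.11 ± 0.14 (SE, adjusted p = 0.0165). Among the genes named for their part in this group's work, htl, the FGF receptor of the early mesoderm, rose by 1.03 ± 0.11 (SE, adjusted p = 0.0307). CHES-1-like, the other forkhead gene followed by the group, differed by -0.08 ± 0.09 (SE, adjusted p = 0.736). No probe set was paired with polo, fz or fz2 in the annotation used, and these genes were not analysed here. The call of jumu was lost with median centring (log2 change 2.33, adjusted p = 0.06) and when any 1 of the 6 arrays was left out (log2 change 2.05 to 2.23, adjusted p 0.0628 to 0.104). With the replicate number as a block it was lost too (log2 change 2.11, adjusted p = 0.238). Over all alternatives its adjusted p ran from 1.28e-18 to 0.238.

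**Figure D1:**
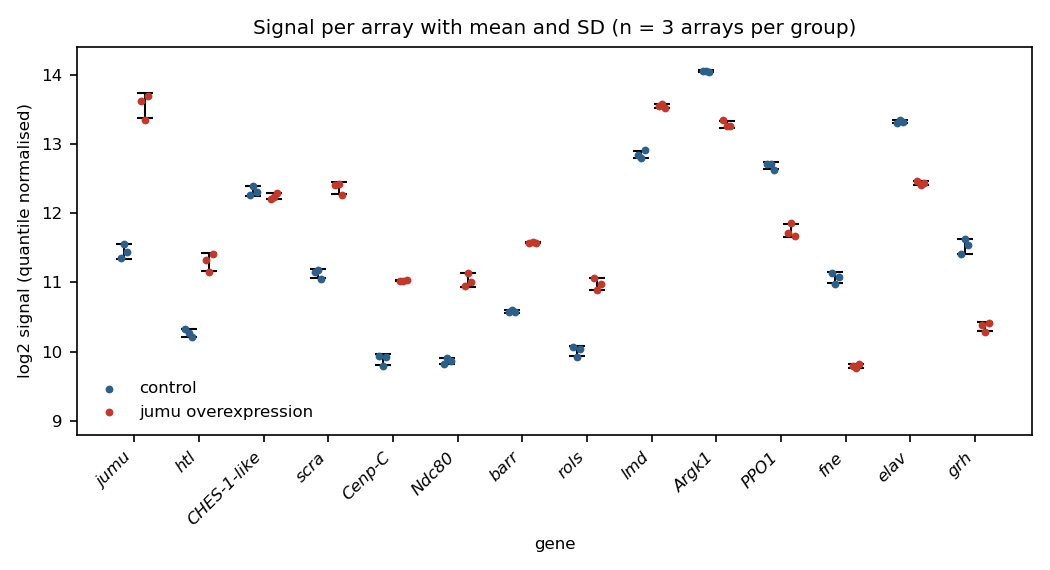
Log2 signal after quantile normalization (vertical axis) of 14 genes (horizontal axis) in the 3 control and 3 jumu overexpression arrays. Points are arrays and black bars are the mean ± SD; jumu lies at 13.56 against 11.45 in controls, and CHES-1-like differs by -0.08.

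With limma, 398 genes changed in the jumu arrays, of which 193 rose and the others fell. The 12 genes with the largest fitted rises, hlk excepted, were near background in the controls, so their rises have no exact size and no order. Below a log2 signal of 6, a level chosen after seeing the data, replicates differed widely, and these genes are set against that level. CG31606 rose from 3.35 ± 2.03 (SD, n = 3) to 12.05 ± 0.03 (SD, n = 3), which is at least 6.05 above it. Likewise Ac78C, an adenylyl cyclase gene, rose to 9.94, CG7778 to 8.18, CG13676 to 9.91, CG14273 to 8.50, CG31468 to 9.24, rdgC to 9.21, the antisense RNA asRNA:Eig63F-2 to 8.33, the lysozyme gene LysX to 6.94, lncRNA:CR32835 to 9.03 and CG4576 to 9.72, each from a control mean under 6. The control signal of hlk was 6.37 ± 0.37 (SD, n = 3), and it rose by 5.71 ± 0.21 (SE). Of the 12 genes with the largest fitted falls, nur alone was above that level in both groups, and fell by 2.15 ± 0.16 (SE) from 10.11 ± 0.18 (SD, n = 3) in controls. CG14535 and CG2962 fell from 6.50 and 6.43 to under 6, by at least 0.50 and 0.43. CG14626, the odorant receptor gene Or24a, CG11322, CG13794, Ugt37C2, the chitin deacetylase gene Cda4, CG14930, mir-4973 and lncRNA:CR34047 fell too, but were under 6 in both groups, and no size is given. The other probe sets of lncRNA:CR34047 differed by -0.13 and -0.24.

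These genes came from 519 probe sets past the threshold, 255 higher and 264 lower, and 3661 probe sets had an unadjusted p under 0.05. In 5441 probe sets (29.0%) the groups did not overlap, where chance gives 10%. Of the 398 genes, 77 had a group mean under 6 and 40 had both group means under it. The counts depended strongly on the arrays kept, on the scaling and on how spread was estimated. Leaving out 1 array left 0 probe sets (jumu replicate 1), 4 (jumu replicate 2 or 3), 12 (control replicate 1), 21 (control replicate 2) or 15 (control replicate 3), and median centring left 13 genes, all higher, whereas an intensity trend in the variance prior gave 2541 genes, 1237 higher and 1304 lower.

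**Figure D2:**
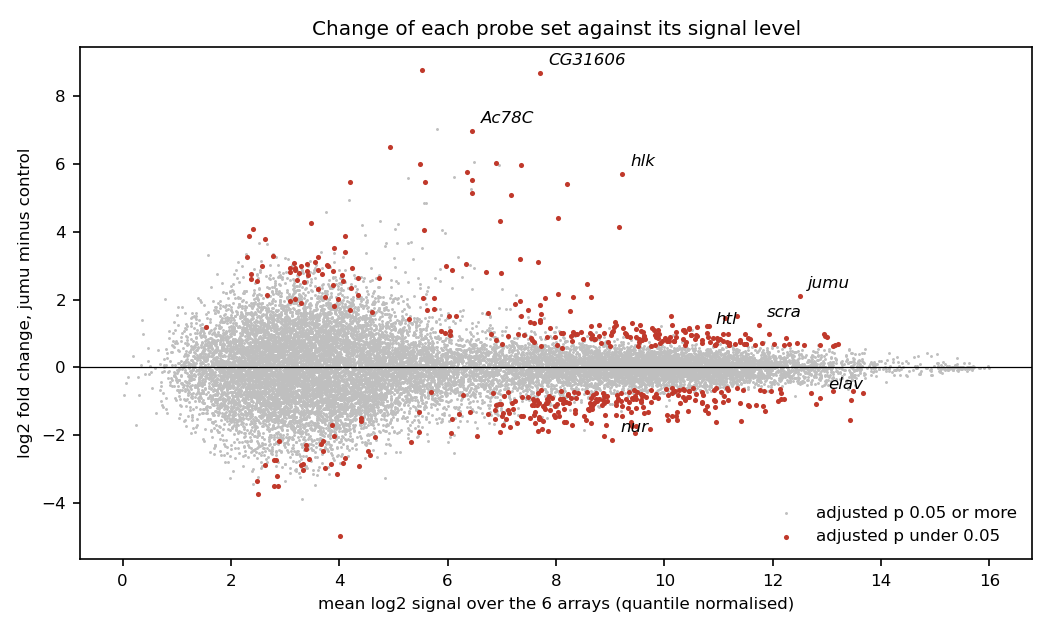
Log2 fold change, jumu minus control (vertical axis), against the mean log2 signal over the 6 arrays (horizontal axis) for the 18769 probe sets. Red points are the 519 probe sets with an adjusted p under 0.05 and grey points the rest; jumu rose by 2.11 and hlk by 5.71.

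Genes of mitosis had the highest median change and the most members past the threshold among the tested lists, although the mean change was higher in the blood cell list (0.75 against 0.63), where it was carried by genes near background in controls; among probe sets above the median level the list Polo and mitosis had a mean of 0.62 and the blood cell list 0.38. Of 48 measured members of the list, 20 rose, 0 fell and 43 had a positive change, with a median log2 change of 0.69. They included the kinetochore and centromere genes Cenp-C (1.14 ± 0.09 SE), Ndc80 (1.17 ± 0.10) and cid (1.16 ± 0.14), scra, which encodes anillin of the cytokinetic ring (1.24 ± 0.10), and the condensin genes barr (0.99 ± 0.09), SMC2 (1.04 ± 0.10) and Cap-G (1.24 ± 0.13). The kinase gene aurB and the mitotic cyclin genes CycB and CycB3 rose by 0.94, 0.65 and 0.71. Adjusted over the list alone, 37 rose and 1 fell. Camera gave an adjusted p of 9.17e-21, and adjusted p = 0.00721 with an estimated correlation, the only list past the threshold in both. With the preset correlation the list also passed in 8 of the 9 other splits of the 6 arrays into 3 and 3 (adjusted p 0.000475 to 0.0573 over the 9), each of which mixes the genotypes and keeps part of the contrast, so the size of that p is no measure of chance with 3 arrays a group. Leaving out any 1 of the 6 arrays, or median centring, left 0 single members past the threshold. The list's mean minus that of other genes was 0.61 to 0.67 without 1 array, against 0.63 with all. Its mean was 0.90 with median centring. In the same arrays the 48 pooled genes of the nervous system and epidermis lists had a median change of -0.49.

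DNA replication and chromatin genes were also higher as groups, by less. In the replication list 2 of 32 measured genes rose and 0 fell (adjusted over the list alone, 11 and 1), with a median of 0.30; both, RPA1 (0.72 ± 0.10) and RPA2 (0.65 ± 0.09), encode subunits of the single-strand DNA binding complex RPA. Camera's adjusted p was 0.000101, and adjusted p = 0.0591 with an estimated correlation. In the chromatin silencing list 1 of 27 rose and 1 fell (adjusted over the list alone, 11 and 2), with a median of 0.26: Su(var)2-HP2 rose by 0.84 ± 0.10 and HP6 fell by 1.56 ± 0.14. This list had an adjusted p of 0.000101, and adjusted p = 0.101 with an estimated correlation. The median of -0.49 in the nervous system and epidermis lists stands beside these groups too.

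Mesodermal groups moved in both directions, again beside neural and epidermal genes with a median of -0.49. Of the muscle founder and fusion genes, 3 of 26 rose and 0 fell (adjusted over the list alone, 4 and 1; median 0.13): the myoblast fusion genes rols (0.97 ± 0.10) and sns (0.94 ± 0.11), and lmd (0.70 ± 0.09), a transcription factor gene of fusion-competent myoblasts. Its adjusted p was 0.0161, and adjusted p = 0.129 with an estimated correlation; without control replicate 1 it was 0.0607. Of the differentiated muscle genes, 3 of 20 fell and 0 rose (adjusted over the list alone, 9 and 1; median -0.44, mean -0.35, which turned to 0.16 and 0.51 with scaling to hybridization and poly-A controls): Argk1, encoding arginine kinase (-0.77 ± 0.09), the muscle LIM protein gene Mlp60A (-0.97 ± 0.12) and the troponin C gene TpnC73F (-0.93 ± 0.14). The list had an adjusted p of 0.00172, and adjusted p = 0.0824 with an estimated correlation. In the visceral mesoderm list 0 of 17 members passed (7 higher and 0 lower at an unadjusted p under 0.05; adjusted over the list alone, 3 higher and 0 lower), and its median was 0.26, with org-1 at 1.05 ± 0.17, bin at 0.67 ± 0.11 and jeb at a log2 signal of 7.51 against 5.92 in controls. Camera placed that list above other genes (adjusted p = 0.00194, and adjusted p = 0.0824 with an estimated correlation). Of the cardiac progenitor and heart genes 0 of 26 passed (7 higher and 2 lower at an unadjusted p under 0.05; adjusted over the list alone, 4 and 2), with bib at 0.68 ± 0.11, toy at -1.16 ± 0.19 and a median of 0.10 (camera adjusted p = 0.0725; over alternatives 0.0172 to 0.283, past the threshold in 6 of 19). The gene tin, on the cardiac and early mesoderm lists, and Mef2, on the latter, had no probe set in the annotation used and were not measured. In the early mesoderm list htl alone rose among 13 (adjusted over the list alone, 4 higher and 1 lower); its median was -0.01 and its mean 0.22 (adjusted p = 0.300). A member near 0, vap, is a gene that was not meant, and without it the median of the 12 others was 0.25 and the mean 0.25 (adjusted p = 0.225). The list passed with median centring (0.0215) and with scaling to hybridization (0.00793) and poly-A controls (0.00468).

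**Figure D3:**
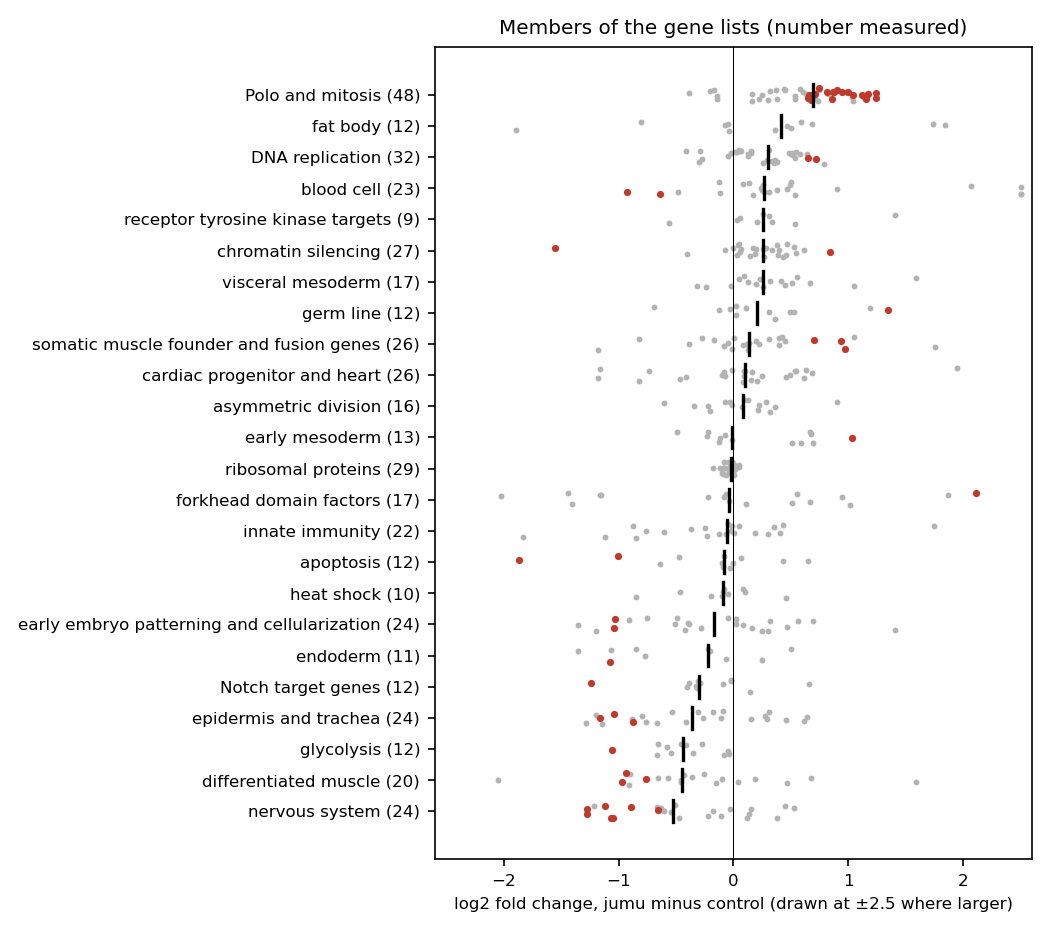
Log2 fold change, jumu minus control (horizontal axis, values beyond 2.5 in size drawn at 2.5), of the measured members of the 24 tested gene lists (vertical axis, with the number measured). Red points have an adjusted p under 0.05, grey points do not and black bars are medians, from 0.69 for mitosis to -0.53 for the nervous system.

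Genes of the nervous system, epidermis and trachea, which mark cells outside the mesoderm, were lower in the jumu arrays, with mean changes of -0.45 and -0.37 that turned to 0.08 and 0.15 with scaling to hybridization controls and to 0.43 and 0.50 with scaling to poly-A controls. Of 24 neural genes 7 fell and 0 rose (adjusted over the list alone, 12 and 2), with a median of -0.53. These were the neuronal RNA-binding protein genes fne (-1.27 ± 0.10) and elav (-0.89 ± 0.09), the transcription factor genes D (-1.27 ± 0.11), nerfin-1 (-1.06 ± 0.09) and SoxN (-0.65 ± 0.09), insb (-1.05 ± 0.10) and the glial gene repo (-1.12 ± 0.15). Their signal in the control arrays was not low, with elav at 13.32. The adjusted p was 0.000101, and adjusted p = 0.0591 with an estimated correlation. Of 24 epidermal and tracheal genes 3 fell and 0 rose (adjusted over the list alone, 11 and 4; median -0.36): grh (-1.16 ± 0.11), kni (-1.04 ± 0.13) and the FGF ligand gene pyr (-0.87 ± 0.12). That list had an adjusted p of 0.0126, and adjusted p = 0.109 with an estimated correlation. No single gene of the nervous system list passed when any 1 array was left out or with median centring. That list's mean minus that of other genes was -0.48 to -0.41 without 1 array, against -0.45 with all. Its mean was -0.22 with median centring.

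Lists of other cell types gave mixed results. In the blood cell list 2 of 23 fell and 0 rose (adjusted over the list alone, 3 lower and 6 higher): PPO1, a prophenoloxidase gene of crystal cells (-0.93 ± 0.10), and the peroxidase gene Pxn (-0.64 ± 0.09). The list's test went the other way, with a median of 0.26 and an adjusted p of 0.00564 for a shift upward, and adjusted p = 0.120 with an estimated correlation. A positive change in He, a hemocyte gene near background in controls (1.69 against 6.65), did not pass (adjusted p = 0.0646). With dim probe sets below the median level left out, the list's mean was 0.38 and its adjusted p 0.0516. The fat body list had 0 of 12 past the threshold (3 higher and 0 lower at an unadjusted p under 0.05; adjusted over the list alone, 3 higher and 0 lower), with srp at 0.51 ± 0.10 and a median of 0.42. In the endoderm list hkb fell by 1.08 ± 0.14 and 0 of 11 rose (adjusted over the list alone, 2 lower and 1 higher; median -0.22). In the germ line list bam, a differentiation gene, rose by 1.35 ± 0.16 and 0 of 12 fell (adjusted over the list alone, 3 higher and 1 lower; median 0.21). Each of these 3 lists had an adjusted p of 0.182. The fat body list passed in 2 of 19 alternatives: fry (0.0193) and camera without control replicate 2 (0.0389). Its mean minus that of other genes ran from 0.18 to 0.45 without 1 array, against 0.28 with all. Among 24 early patterning genes opa (-1.03 ± 0.12) and kni fell and 0 rose (adjusted over the list alone, 6 lower and 1 higher), with a median of -0.17 and an adjusted p of 0.182.

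Metabolic and signalling lists were called beside the same median of -0.49 in neural and epidermal genes. All 12 measured glycolysis genes had a negative change, with a median of -0.44 (mean -0.43, turning to 0.14 and 0.50 with scaling to hybridization and poly-A controls), and 1, the triosephosphate isomerase gene Tpi, fell (-1.06 ± 0.16; adjusted over the list alone, 8 lower and 0 higher). Camera's adjusted p was 0.000101, and adjusted p = 0.0591 with an estimated correlation. Of 12 genes on the Notch target list, of which her was not meant, Hey fell by 1.24 ± 0.11 and 0 rose (adjusted over the list alone, 4 lower and 0 higher); the median was -0.30 and the mean -0.22, which turned to 0.04 with median centring and to 0.33 and 0.69 with the control scalings, and E(spl)m3-HLH was at -0.32 ± 0.09. The list had an adjusted p of 0.0126, and adjusted p = 0.268 with an estimated correlation, and the call was lost with median centring (0.464). Without her the median was -0.31 and the mean -0.23 (adjusted p = 0.00867, and adjusted p = 0.283 with an estimated correlation). Of 9 targets of receptor tyrosine kinase signalling 0 passed (4 higher and 0 lower at an unadjusted p under 0.05; adjusted over the list alone, 1 higher and 0 lower), with the ligand gene spi at 0.53 ± 0.09 and a median of 0.26. That list had an adjusted p of 0.0185, and adjusted p = 0.135 with an estimated correlation; it was 0.0507 with median centring and 0.0772 without control replicate 1.

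The remaining lists were not past the threshold as reported. Among 17 forkhead genes jumu alone rose and 0 fell (adjusted over the list alone, 2 higher and 0 lower); the median was -0.04 while the mean and the test pointed up (adjusted p = 0.765). In the apoptosis list grim, a cell death activator (-1.87 ± 0.27), and grnd, a TNF receptor gene (from 7.75 to 6.75), fell and 0 of 12 rose (adjusted over the list alone, 4 lower and 2 higher; median -0.09, adjusted p = 0.182). The lists for asymmetric division, heat shock and innate immunity had 0 genes past the threshold among 16, 10 and 22, with medians of 0.08, -0.09 and -0.06 and adjusted p of 0.336, 0.477 and 0.765. Adjusted over the list alone, 1 gene was lower in the first (pros), 1 lower in the second (Hsp60A, -0.84 ± 0.13) and 1 higher in the last (PGRP-SB1, 1.75 ± 0.30), and at an unadjusted p under 0.05 these lists had 5, 2 and 5 genes. The 29 measured ribosomal protein genes had a median of -0.02 (adjusted p = 0.320; mean -0.03, turning to 0.23 and 0.58 with the control scalings). As a list they were lower without the quantile step (mean -0.34, adjusted p = 2.79e-08) and with median centring (mean -0.07, adjusted p = 0.00756). With the poly-A controls camera, which works on t values, called the list upward (adjusted p = 0.0440), although its mean lay 0.19 below that of other genes. Of single members 0 passed at the adjusted threshold, adjusted over the list alone or at an unadjusted p under 0.05. The variance prior limits what this count can show. RpS21 differed by -0.11 with no overlap between groups and SDs of 0.03 and 0.02, but its SE was 0.09. Of the Wnt and FGF receptor list 3 genes were measured, of which htl rose (adjusted over the list alone, 1 higher and 0 lower). The transgene marker list had 2, ry at 0.41 ± 0.13 and y, near background in both groups, with 0 past the threshold, 0 adjusted over the list alone and 1 at an unadjusted p under 0.05. Both lists were too short to test.

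Scaling sets the zero of all these changes. Relative to quantile normalization, median centring moved the median change over all probe sets to 0.16 and the values without a quantile step moved it to -0.11. Spiked-in RNAs were lower in the jumu arrays, by -0.57 (pooled SD 0.17) for the hybridization controls and -0.92 (pooled SD 0.04) for the poly-A controls in the deposited values, each with an exact two-sided permutation p of 0.1, the smallest that 3 against 3 arrays allow. Scaling to them would move the median change to 0.46 or 0.81, with 23 genes higher and 0 lower by the former and 5781 higher and 83 lower by the latter. With either of these scalings all 24 tested lists had a mean change above 0, and camera, which sets a list against the other genes, no longer called differentiated muscle (adjusted p 0.0763 and 0.761), epidermis and trachea (0.0763 and 0.353), Notch targets (0.841 and 0.292) or receptor tyrosine kinase targets (0.0527 and 0.0829) by either. Glycolysis (0.511 and 0.598) was lost by both and the nervous system (0.294) by the poly-A controls alone. Lists were also gained: early mesoderm and asymmetric division (0.0479 with median centring, 0.0164 and 0.00461 with the control scalings) by all 3 shifts of the zero, germ line (0.0473) by median centring, cardiac progenitor and heart (0.0391) by the values without a quantile step, and ribosomal proteins by median centring, the poly-A controls and the values without a quantile step.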

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

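The shifts to spiked-in controls, the combinations with the intensity trend and the lists without vap and her were chosen after seeing the data; the other alternatives were planned. Counts of probe sets, genes, higher genes, lower genes, mitosis genes that rose and neural genes that fell (519 probe sets, 398 genes, 193 of them higher, 20 mitosis and 7 neural genes as reported) stayed within 1.5 times without the quantile step, with array weights and with the unequal-variance test. They became 20, 13, 13, 0, 0 and 0 with median centring; 2581, 2119, 996, 1123, 37 and 12 for probe sets above the median level; 1451, 1174, 551, 623, 31 and 12 without the dimmest 25% of probe sets; 3096, 2541, 1237, 1304, 37 and 11 with an intensity trend; 3094, 2518, 1219, 1299, 38 and 11 with trend and robust estimation; and 146, 109, 51, 58, 7 and 4 with treat at 1.2-fold. The mean over probe sets gave 860 genes, 399 higher and 461 lower, and 11 neural genes. Shifts to the hybridization controls gave 31, 23, 23, 0, 0 and 0, and to the poly-A controls 7425, 5864, 5781, 83, 44 and 0. Leaving out 1 array gave 0 to 21 probe sets, 0 to 16 genes, 0 to 16 higher, 0 to 1 lower, and 0 mitosis and 0 neural genes, with fewer arrays behind each spread; without jumu replicate 1, where 0 probe sets passed in limma, 2959 had an unadjusted p under 0.05. With the intensity trend, leaving out 1 array gave 2537 to 2794 probe sets, 2092 to 2281 genes, 989 to 1150 higher, 1100 to 1157 lower, 36 to 38 mitosis genes and 11 neural genes. The trend with median centring gave 2357 probe sets, 1906 genes, 1652 higher and 39 mitosis genes. Of the 519 probe sets, 464 were also past the threshold with the trend, all 464 with the same sign. The cause was not tested beyond the simulation, where the trend recovered 42 of 62 changes of 1 log2 unit above the median level against 21.

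Over all probe sets, deviations of same-numbered arrays from their group means correlated at -0.0118, 0.0026 and 0.00975. Most probe sets had a mean log2 signal under 6, where replicates differed widely. A batch shared by same-numbered arrays could therefore go unseen, and whether the numbers pair the samples stays open. With the number as a replicate block limma called 0 probe sets, 0 genes, 0 higher, 0 lower, 0 mitosis and 0 neural genes, while 2888 probe sets had an unadjusted p under 0.05 and the unequal-variance test without a block called 453; jumu kept 2.11 with an adjusted p of 0.238. The block with the intensity trend gave 2955 probe sets, 2436 genes, 1185 higher, 1251 lower, 37 mitosis and 11 neural genes.

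The change of jumu was 2.33 (adjusted p = 0.06) with median centring and 2.05 to 2.23 without 1 array. The 12 lists past the threshold stayed 12 without vap and her, and became 1 with an estimated correlation, 20 with fry, which does not compare a list with other genes, and 10 to 13 without 1 array. The gap in r within and between genotypes (0.0081) was 0.0269 above the median level, 0.0143 without the dimmest 25% and 0.00551 to 0.01 without 1 array. Named genes past the threshold as reported or in an alternative changed sign there with the poly-A shift only. Argk1, TpnC73F, Pxn and pyr, which fell as reported, were at 0.071, 0.020, 0.29 and 0.0033 and no longer past the threshold. Genes not past it as reported became higher: CHES-1-like at 0.86, sna 0.45, mira 0.61, E(spl)mbeta-HLH 0.53, E(spl)m3-HLH 0.59, E(spl)m2-BFM 0.56, Hsp26 0.75, Pepck1 0.38, RpL17 0.59, RpL3 0.59 and RpLP0 0.54. Camera's direction turned for Notch targets with both shifts (list mean minus other genes -0.084 in each), and for glycolysis (-0.28) and ribosomal proteins (-0.19) with poly-A, although these differences stayed negative. Among lists past the threshold neither as reported nor in the alternative, it also turned for forkhead factors and heat shock with both shifts, heat shock with median centring, ribosomal proteins with the hybridization shift, apoptosis with poly-A and innate immunity above the median level. Signal over background limits dim genes most: below the median level the simulation recovered 1 of 57 changes of 2 log2 units.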

Other observations

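The tests in this part were chosen after the results were seen, except those of other splits of the arrays, which were planned. Further gene groups were put together after the data were seen, partly from genes already known to have passed, so their tests are not independent of the calls. Of 45 spindle, centriole and kinetochore genes outside the mitosis list, 15 rose and 0 fell, with a median of 0.46. Cks30A, a partner of the mitotic kinase Cdk1, rose by 1.45 ± 0.09 (SE), the centriole genes Sas-4 by 1.12 ± 0.12, Sas-6 by 1.00 ± 0.13 and spd-2 by 1.10 ± 0.10, and the kinetochore gene Spc105R by 0.99 ± 0.12. Camera gave an adjusted p of 2.47e-17, and adjusted p = 0.00511 with an estimated correlation. Of 18 cohesin and anaphase-promoting complex genes 1 rose (APC4, 0.65 ± 0.09) and 0 fell (median 0.15, adjusted p = 0.0042, and adjusted p = 0.0893 with an estimated correlation). Of 20 nuclear pore genes Nup35 (0.65 ± 0.09) and Nup188 (0.62 ± 0.09) rose and 0 fell (median 0.35, adjusted p = 2.11e-07, and adjusted p = 0.06 with an estimated correlation). Of 40 proteasome genes 0 passed in limma and 12 with an intensity trend (median 0.12, adjusted p = 0.0195, and adjusted p = 0.0893 with an estimated correlation).

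Mitochondrial and vacuolar ATPase genes were lower relative to other genes in camera. The sign of their medians is set by the scaling: the medians of the mitochondrial ribosome, oxidative phosphorylation and vacuolar ATPase groups turned to 0.31, 0.26 and 0.24 with scaling to hybridization controls and to 0.67, 0.61 and 0.59 with poly-A controls, and the first to 0.02 with median centring. Of 69 mitochondrial ribosome genes 57 had a negative change, 1 fell (mRpL51, -0.62 ± 0.09) and 1 rose (mRpL48, 0.79 ± 0.12), with a median of -0.28, an adjusted p of 5.51e-10, and adjusted p = 0.06 with an estimated correlation. Of 69 oxidative phosphorylation genes 59 had a negative change and 0 passed in limma, while 36 fell with an intensity trend (median -0.24, adjusted p = 2.81e-08, and adjusted p = 0.06 with an estimated correlation). Of 31 vacuolar ATPase genes Vha13 fell (-0.62 ± 0.09) and 0 rose (median -0.29, adjusted p = 0.00441, and adjusted p = 0.0893 with an estimated correlation). The Osiris genes (Osi5 rose and Osi6 fell among 24), cuticle protein genes (0 of 66 in limma, 1 with an intensity trend) and odorant and gustatory receptors (2 rose and 1 fell among 112) had adjusted p of 0.990, 0.244 and 0.990. Among 6 genes known from larval plasmatocytes, a blood cell type, Pxn fell, while He (1.69 in controls against 6.65, adjusted p = 0.0646), Hml (3.13 against 7.99, adjusted p = 0.105) and NimC1 (3.66 against 6.25, adjusted p = 0.275) were near background in controls and did not pass; with an intensity trend these 3 did (adjusted p 0.00103, 0.000141 and 0.0448). The group had an adjusted p of 0.117.

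Higher mitosis genes could come from the sort or the age of the embryos as well as from an effect of Jumu, which was not tested by itself. Fewer cells from outside the mesoderm would raise genes made in the mesoderm alone at least as much. The 73 pooled mesodermal genes had a median change of 0.15 against 0.69 for mitosis, but their SD of 0.55 reaches past it (their median absolute deviation of 0.40 does not). That SD is the spread of the members and not the error of their median. The pool also held genes near background in controls, such as sli (2.00) and H15 (2.76), and pnr, which is on the epidermis list too. Neural and epidermal genes were lower (-0.49), so purity cannot be told apart from an effect of Jumu. A difference between the genotypes in copies of driver or GFP reporter could change which cells passed the sort, and was not tested. Of the 24 measured genes of the nervous system and the epidermis lists, 2 and 4 were also on another list, and elav (13.32) and grh (11.52) had the brightest control signal in each. A sort of mesodermal cells would be meant to remove neural and epidermal cells, and signals this bright in sorted samples leave open how many remained. Younger jumu embryos would show higher early patterning genes and lower muscle genes: the former had a median of -0.17 and the latter -0.44, which leaves age open. Among the 10 splits of the 6 arrays 1, the real split, reached its 519 probe sets (highest other 1) and 1, the real split, reached its 12 lists (highest other 2), but 10 splits are too few for a share under 0.05.

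Genes with a fitted rise over 4-fold and a control signal below the median level of all probe sets numbered 41. A block on 1 chromosome arm carried by 1 stock as the source of most of them is argued against by their spread. The arm with most of them held 14, or 34.1%. Genes were counted by arm, so a difference over both arms of 1 chromosome was not tested and stays open. This count cannot exclude a block behind part of them, and genes that fell were not counted. Several short regions that differ between stocks may account for part, since 6 pairs of these genes lay within 5 measured genes of each other (CG14273, CG7778 and Mur29B; CG33469 and CG33468; bab1 and LysX; CG13813 and rdgC), against a 95th percentile of 2 in 10000 random sets matched on level (one-sided permutation p = 0.0002), although neighbours switched on together by Jumu would give the same count. A sequence variant under the probes stays open, as 38 of these genes had no other probe set, although each of the 3 that did had 1 that was higher (CG31606 from 1.13 to 9.91, adjusted p = 0.00356; rdgC from 2.27 to 9.32, adjusted p = 0.0512; SK from 4.46 to 7.46, adjusted p = 0.0383), which goes against a variant under 1 probe set in them; 2 more of SK were near background in both groups, and the median change of all 5 was 2.99 (median absolute deviation 4.83). An effect of Jumu on the genes stays open as well.

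The lower signal of spiked-in RNAs in the jumu arrays may mark a difference in how the samples were prepared. A different dose of the poly-A spikes alone is argued against, because the hybridization controls were lower too, by -0.57 with a pooled SD of 0.17. A difference in RNA integrity stays open: the 3' minus 5' difference of actin was higher in the jumu arrays by 0.11 (pooled SD 0.06) with no overlap, those of GAPDH and eIF-4a differed by -0.06 (pooled SD 0.36) and -0.08 (pooled SD 0.13), and the mean of -0.0058 over genes that go both ways does not decide. Separate preparation of the arrays of each genotype cannot be told apart from genotype, since the poly-A controls differed by -0.92 with no overlap between groups, and more endogenous RNA per cell in the jumu group was not tested.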
